A study of Caenorhabditis elegans with 2 samples.

How the data were processed

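Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Caenorhabditis elegans L4 larvae, 48 hours old. The animals carried the endogenous set-16 gene fused by CRISPR to TY1, EGFP and 3xFLAG tags, and chromatin was sheared by sonication and pulled down through the GFP tag, per the labels. The series holds 2 biological replicates of 1 group, so no contrast between conditions exists. A control experiment is named in the labels and was not analysed here.

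The 8 peak lists on the ce11 genome build (the same assembly as WBcel235) used here were a ranked and a thresholded list for each replicate, and 2 further pairs made from both libraries together. The deposited lists were derived from filtered alignments and a control, per the deposited readme. The aligner, the peak caller and their versions are not given in the sources used here. Each deposited peak has a signal as the authors' caller gave it, whose scale is not given in the sources used here. At matched peaks the conservative signal was a median of 0.997 times the sum of the replicate signals, so it is not a ratio averaged over libraries, and its values are set side by side only within a list. Each deposited peak also has a score, which is a scaled irreproducible discovery rate (IDR) with a highest value of 1000. The lowest score in every thresholded list was 830, which corresponds to a global IDR of 0.01. Every thresholded peak was found in its ranked list. Of the ranked peaks within that limit, 102 were missing from the conservative list, 110 from the second whole-series list, 108 from replicate 1 and 89 from replicate 2, and the reason is not given in the sources used here. Read depth is unknown because the files hold no read counts. Each replicate has a list of its own, and the whole-series lists were made from both libraries together, per the deposited readme.

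The conservative whole-series list was the main peak set. Genes and chromosome sequences came from the Ensembl annotation and RefSeq sequence of WBcel235, and every peak lay within the reference chromosome lengths. A gene start window ran from 1000 bp upstream to 200 bp downstream of the annotated start of each of 19973 protein-coding genes on the 6 nuclear chromosomes. Annotated starts are often trans-splice sites in this species and can lie downstream of the site of initiation. A gene had a promoter peak if a summit fell in its window. The chromosome centre ran from 33.3% to 66.7% of the chromosome length.

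Replicate lists were compared by overlap of at least 1 bp, beside 1000 circular shifts of replicate 2 along each chromosome (one-sided permutation test). Signals were compared across ranked peaks matched by summits within 100 bp at conservative peaks. Shares of summits were tested with the two-sided exact binomial test. Promoter peaks in 26 gene lists and in 175 gene name classes of at least 10 members were tested with the two-sided Fisher exact test against all other protein-coding genes, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. The 20 consensus motifs fixed in advance were searched within 100 bp of promoter summits and in control windows at the same offsets from gene starts that held no ranked peak, matched on GC content in strata of 2%. Lists, classes, motifs and planned tests were set before the data were examined.

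Tests stratified on GC content were added after seeing the data. The genome was divided into tiles of 200 bp, and the number of tiles with a summit in a category was compared with its exact distribution given the number in each stratum of 2% GC. For genes, strata were those of the highest GC content within 100 bp of any point of the gene start window, taken every 25 bp. The list tests were tested on simulated calls over 19973 genes and 26 lists, in 50 runs each. With calls set by GC content and no list changed, the Fisher test called 3.98 lists per run and the stratified test called 0. With calls unrelated to GC content, both called 0.08 lists per run. A list of 80 genes given 4 times the odds was called in 22 of 50 runs by the stratified test, and one given 10 times the odds in 50. Where calls were set by GC content, they came from the same GC measure that defined the strata. Each gene was called independently, and the changed list was of genes drawn at random. The runs therefore do not show how the test behaves where calls follow GC content in another way or where genes share summits.

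The genes named were fixed by rule: the 15 genes with the highest-signal promoter peaks that also had a promoter peak in both replicate lists, all members of the SET-16 and COMPASS list, up to 4 members with the highest signal in each list above background, up to 3 in a list below it, and up to 3 in each of the 5 classes above background with the lowest p. The 5 peaks of highest signal were named by position. Intervals are exact 95% binomial (Clopper-Pearson) intervals and cover counting error only. Neighbouring peaks and genes of one family are not independent, so p-values describe these calls and not the spread between animals. Alternatives included the second list, the upper part of the list by signal, each replicate alone, other windows, assignments, backgrounds and control windows. The upper part was the 2898 of 5795 conservative peaks with the highest signal. It is called the peaks of highest signal below where no number is given. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.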

Results

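SET-16 is the worm counterpart of the mammalian MLL3 and MLL4 histone H3 lysine 4 methyltransferases. Its chromatin occupancy was profiled in L4 larvae of a strain carrying a GFP-tagged set-16 gene, by ChIP-seq with an antibody against GFP, in 2 biological replicates of 1 group at 48 hours. The comparisons are between the replicates, and between peak positions and the genome. The conservative whole-series list held 5795 peaks with a median width of 437 bp, covering 2.01 Mb or 2.00% of the nuclear genome. Replicate 1 gave 5876 peaks, replicate 2 gave 4377, and the second whole-series list held 6905. In the conservative list, 5483 intervals were distinct, because some intervals carried several summits. Read depth is unknown, so the difference in length between the replicate lists cannot be set against it. There is 1 value per list and no spread over replicates for values taken from the whole-series lists.

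Most sites called in the shorter replicate list were also called in the other. Of the 4377 peaks of replicate 2, 3504 (80.1%, interval 78.8 to 81.2) overlapped a peak of replicate 1. In the other direction, 3688 of 5876 (62.8%, interval 61.5 to 64) were shared. Circular shifts gave means of 4.15% and 3.25%, and none of 1000 reached the observed shares (permutation p = 0.001 for each, the smallest they can give, one-sided). The shifts did not hold GC content fixed. Counted by tiles of 200 bp, 67.6% of those with a replicate 2 summit also held one of replicate 1. From GC content alone 32.3% were expected, and 34.7% with GC content of the surrounding kilobase also held fixed. Among conservative peaks, 3584 (61.8%) overlapped a thresholded peak in both replicates, 1181 in replicate 1 only, 448 in replicate 2 only and 582 in neither. Across 5278 matched peaks, which are not independent replicates, signal correlated with a Spearman rho of 0.709 and a Pearson r of 0.781 on the log10 scale. Signal also followed GC content within 100 bp of the summit, with a rho of 0.696 in replicate 1 and 0.436 in replicate 2.

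**Figure D1:**
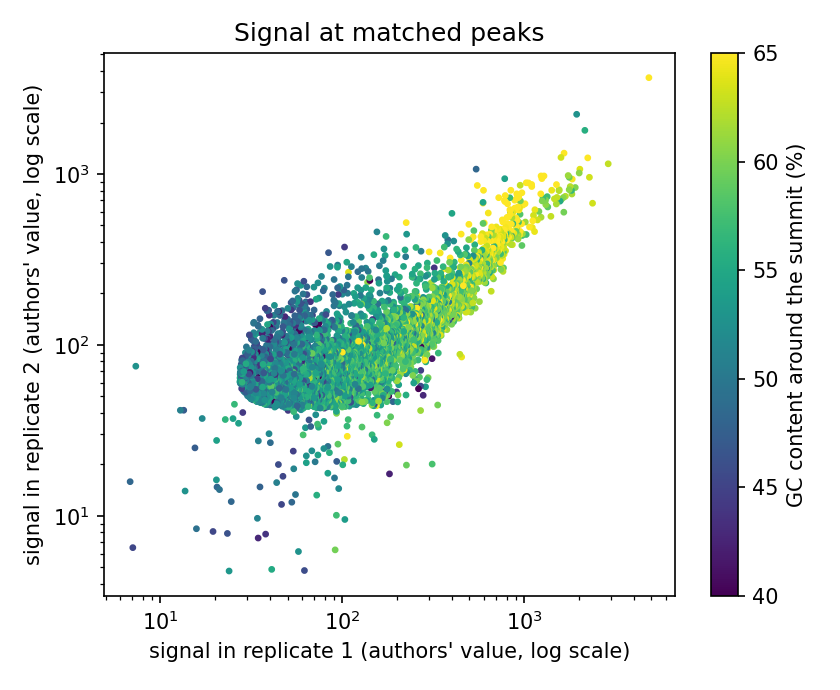
Signal in replicate 1 (x axis) and replicate 2 (y axis), both the authors' own values on log scales, at 5278 matched peaks, 1 point per peak, coloured by GC content around the summit in percent. The points rise together with a Spearman rho of 0.709, and the points of highest signal lie at high GC content.

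The 5 peaks of highest signal had summits in intergenic DNA or introns. Intergenic here means outside protein-coding genes, so it includes noncoding genes. The peak of highest signal (8482 in the conservative list) spanned chromosome II 2973739 to 2974530 on ce11, in intergenic DNA 2464 bp from the nearest gene start, that of the nuclear hormone receptor gene nhr-88. The next, with a signal of 4169, lay on chromosome V 13645750 to 13646435, in intergenic DNA 88 bp from the noncoding RNA gene H37A05.5. The third lay in an intron of ppfr-1, a phosphatase regulatory subunit gene, on chromosome I 9380974 to 9381982, with a signal of 4018. The fourth lay in an intron of pqn-41 on chromosome III 1923331 to 1924098, with a signal of 3933. The fifth spanned chromosome III 10633948 to 10634490, with a signal of 3469. Its summit lay 714 bp upstream of the start of Y39A1A.9 and 0 bp from the noncoding RNA gene Y39A1A.28. All 5 were called in both replicates, and their GC content within 100 bp of the summit ran from 55.2% to 69.7%.

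Peaks were concentrated in GC-rich DNA. The median GC content around conservative summits was 54.7%, as it was in each replicate list, against 34.8% at 20000 random positions, of which 95% of values lay below 47.8%. Among tiles of 200 bp with under 30% GC, 0.0108% held a conservative summit. The share was 0.382% at 40 to 45% GC, 18.4% (interval 17.7 to 19.1) at 50 to 55%, and 66.6% (interval 63.4 to 69.8) at 60% or more. In the last class it was 70.6% in replicate 1 and 63.4% in replicate 2. Coding exons held 2648 summits (45.7%), against 24.6% of the genome (exact binomial p = 4.9e-265). With GC content held fixed, coding exon tiles held 2581 summits where 2849 were expected, a ratio of 0.906 (exact stratified p = 2.7e-17), so the direction turned.

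**Figure D2:**
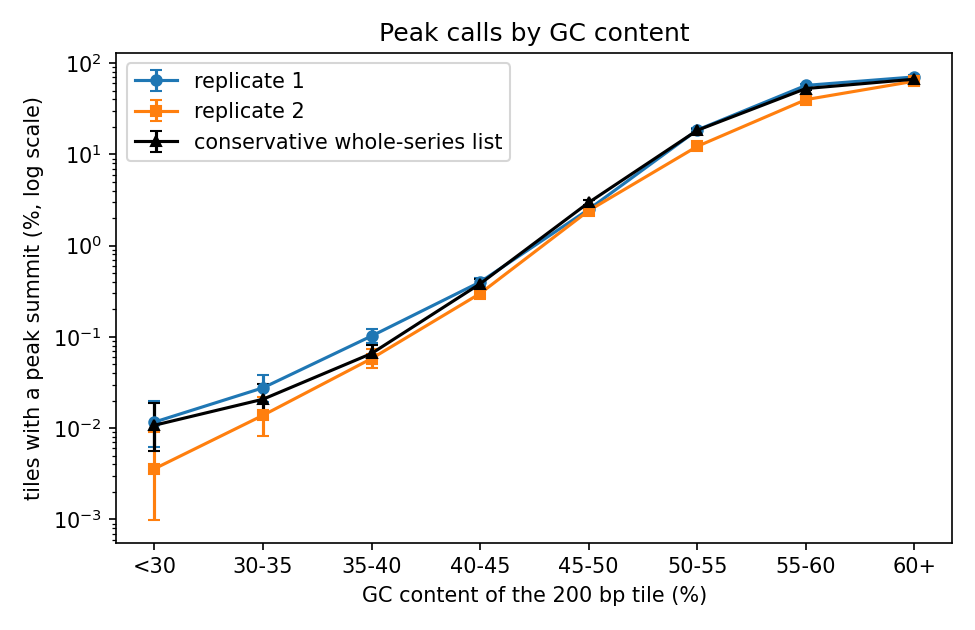
Percentage of 200 bp genome tiles holding a peak summit (y axis, log scale) by GC content of the tile in percent (x axis), for each replicate list and the conservative list, with exact 95% intervals as bars. In the conservative list the share rises from 0.0108% under 30% GC to 66.6% at 60% GC or more.

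The share of summits at gene starts was close to that of the genome. Gene start windows held 1287 of 5795 summits (22.2%, interval 21.1 to 23.3) and made up 21.5% of the genome (fold 1.03, exact binomial p = 0.16). In replicate 2 alone the share was 25% (fold 1.16, exact binomial p = 2.7e-08), and in replicate 1 alone 21.6% (fold 1.01, p = 0.73). The difference between the replicates was not tested. Against tiles of the same GC content, gene start windows held more summits than expected (1275 against 1034, ratio 1.23, exact stratified p = 6.9e-22).

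Peaks were sparse in autosome centres and dense on the arms. Of 4851 autosomal peaks, 826 (17%, interval 16 to 18.1) lay in the chromosome centres, where 38.1% of autosomal gene starts lie (fold 0.447, exact binomial p = 1.6e-225). The centres also held 17.1% of autosomal tiles with 50% GC or more, and against tiles of the same GC content the ratio was 0.906 (exact stratified p = 2.0e-04). In replicate 1 alone that call was lost (ratio 0.993, exact stratified p = 0.77), and in replicate 2 alone the direction turned (1.07, exact stratified p = 0.018). Chromosome X held 944 peaks (16.3%, interval 15.3 to 17.3), below its 17.7% of genome length (fold 0.922, exact binomial p = 0.0056) and above its 13.7% of gene starts (fold 1.19, p = 1.5e-08). The call against genome length was lost in replicate 2 alone (fold 0.980, exact binomial p = 0.55) and for the 2898 peaks of highest signal (fold 0.943, exact binomial p = 0.17). Against tiles of the same GC content, the ratio for X was 1.03 (exact stratified p = 0.19), 1.05 in replicate 1 alone (exact stratified p = 0.041) and 1.10 in replicate 2 alone (exact stratified p = 7.5e-04). By density, chromosome I held 69.5 peaks per Mb and chromosome V 46.5.

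**Figure D3:**
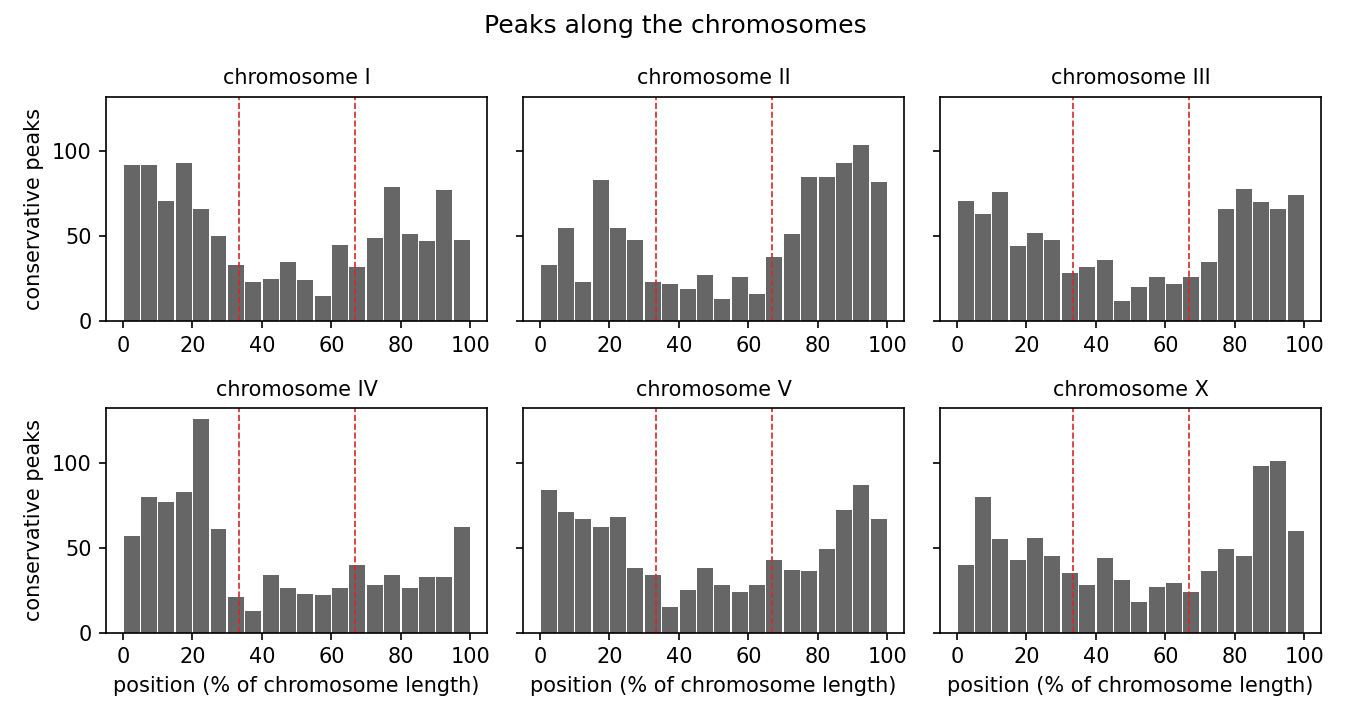
Number of conservative peaks (y axis) in each of 20 equal parts of each chromosome (x axis, position in percent of length). Dashed lines mark the centre, from 33.3% to 66.7% of length, which holds 17% of the autosomal peaks.

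A promoter peak was present at 1397 of 19973 protein-coding genes (6.99%). Replicate 1 gave 1347 such genes, replicate 2 gave 1209, and 871 were in both. Among the 15 genes with the strongest promoter peaks were egl-30, the Gq alpha subunit (signal 2215, summit 49 bp from the gene start), gsa-1, the Gs alpha subunit (2590, 222 bp), grk-1, a G protein-coupled receptor kinase (2750, 511 bp), and pde-6, a phosphodiesterase (3066). The pde-6 summit, on chromosome I at 882817, also lay in the window of Y95B8A.6, which is transcribed in the opposite direction. The highest was at Y39A1A.9. Also in the group were ntl-2, a CCR4-NOT component (2733), and myrf-1, a membrane-bound transcription factor (2626), with the MADF-domain gene madf-9 at 2367. The dynein light chain gene dlc-1 and the complex I gene nduf-2.2 shared a summit with a signal of 2352. The endoplasmic reticulum chaperone gene hsp-3 on chromosome X (6089028 to 6092124) had a summit 17 bp from its start with a signal of 2223. The others were Y48G8AR.8 (2963), C34D10.5 (2834) and Y59A8B.24 (2352). GC content at these summits ran from 60.2% to 69.7%.

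Of the 11 members of the SET-16 and COMPASS list, which holds H3K4 methyltransferases and their partners, 2 had a promoter peak, against 6.99% of other genes (odds ratio 2.96, adjusted Fisher exact p = 0.35). The set-16 gene itself (WBGene00011729, chromosome III 13643916 to 13656637) had a summit 945 bp upstream of its start with a signal of 733, and was called in both replicates. The gene of the shared subunit ash-2 (chromosome II 11979838 to 11989050) had a summit 973 bp upstream with a signal of 51.2, and was called in the window in neither replicate list. No promoter peak was called at set-2, cfp-1, dpy-30, rbbp-5, wdr-5.1, set-17, set-30, pis-1 or utx-1, the last encoding an H3K27 demethylase.

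Genes of the lists for ribosomal proteins, chaperones and the unfolded protein response, and mitochondrial electron transport had promoter peaks more often than other genes. Of 76 ribosomal protein genes, 19 had one (25%, interval 15.8 to 36.3, odds ratio 4.48, adjusted exact p = 5.3e-06). The odds ratio was 2.87 in replicate 1 alone, with 13 genes, and 8.72 in replicate 2 alone, with 27, and the difference was not tested. Examples were rpl-7 (signal 537), rpl-3 (478), rpl-41.2 (399) and rpl-43 (296). Of 40 chaperone and unfolded protein response genes, 13 had one (32.5%, interval 18.6 to 49.1, odds ratio 6.45, adjusted exact p = 9.5e-06). After hsp-3 came the protein disulfide isomerase gene pdi-2 (1352), the stress transcription factor gene atf-6 (930) and the mitochondrial chaperonin gene hsp-60 (619). Of 31 mitochondrial electron transport genes, 8 had one (25.8%, interval 11.9 to 44.6, odds ratio 4.65, adjusted exact p = 0.0045), among them cox-5B (266), cyc-2.1, a cytochrome c (228), and the ATP synthase genes atp-4 (224) and atp-1 (210). In strata of GC content these lists had 1.93, 2.26 and 2.34 times the expected number of genes with a peak (adjusted exact stratified p = 0.0049, 5.8e-04 and 0.032). The electron transport call was lost in replicate 1 alone (adjusted exact p = 0.059). Against genes with a ranked peak in the window as background, all 3 calls were lost: odds ratio 1.39 for ribosomal proteins, 2.80 for chaperones and 1.84 for electron transport (adjusted exact p = 0.57, 0.077 and 0.57). The ranked peaks come from the same libraries as the calls. A call lost against them, here or below, therefore does not show that a list matches other genes. With other peak sets and gene start windows that kept the call, the odds ratio ran from 4.17 to 9.81 for chaperones and from 2.83 to 7.75 for electron transport.

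Muscle, neuronal and histone genes also had promoter peaks more often than other genes, but their calls were lost in strata of GC content. Of 28 muscle genes, 12 had one (42.9%, odds ratio 10.1, adjusted exact p = 1.2e-06). These included act-4, an actin (582), unc-60, a cofilin (502), unc-54, the major myosin heavy chain (451), and unc-15, paramyosin (175). Of 30 neuronal genes, 7 had one (23.3%, odds ratio 4.06, adjusted exact p = 0.015), including ida-1 (555), the proprotein convertase gene egl-3 (348), unc-10 (283) and egl-21 (149). Of 72 histone genes, 21 had one (29.2%, odds ratio 5.54, adjusted exact p = 1.5e-07), including the divergent pairs his-1 and his-2 (346) and his-38 and his-40 (260). In GC strata the ratios were 1.44 for muscle (adjusted exact p = 0.21), 1.89 for neurons (adjusted exact p = 0.12) and 0.689 for histones (adjusted exact p = 0.059). The muscle and neuronal calls were also lost for the 2898 peaks of highest signal (adjusted exact p = 0.074 and 0.27), and the neuronal call in replicate 2 alone (adjusted exact p = 0.12). With other peak sets, gene start windows and backgrounds that kept the call, the odds ratio ran from 4.85 to 15.1 for muscle and from 2.14 to 8.67 for histones. Against genes with a ranked peak in the window the neuronal call was lost at an odds ratio of 4.52 (adjusted exact p = 0.077). Histone genes are near-identical copies whose reads can be shared, so the ranks among them are uncertain.

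Chemoreceptor genes, a large family with most members expressed in few neurons, had promoter peaks less often than other genes. Of 1309, 27 had one (2.06%, interval 1.36 to 2.99, odds ratio 0.266, adjusted exact p = 4.1e-15), and in GC strata the ratio was 0.520 (adjusted exact p = 4.8e-06). The strongest were srh-18 (1184), sri-71 (683) and sri-37 (601). The other 18 lists, among them those for intestine, germline, vulval signalling, Wnt and Hox genes, did not pass the threshold. Of these, C-type lectins passed for the peaks of highest signal (odds ratio 0.106, adjusted exact p = 0.014). Cuticle collagens turned from 0.717 to 2.93 with a window of 2000 bp upstream and 500 bp downstream (adjusted exact p = 1.6e-07) and to 17.2 with the nearest gene start within 1000 bp in place of the window (adjusted exact p = 5.6e-60). F-box proteins passed below background in both (0.478 and 0.436), splicing factors (3.01) and cell cycle genes (3.15) in the first, and vitellogenins (9.71), hypodermis (8.54) and sperm (4) in the second. Against genes with any ranked peak in the window as background, 2 of the 7 lists kept the call, histones and muscle, and the chemoreceptor odds ratio was 0.902 (adjusted exact p = 0.88). With other peak sets and gene start windows it ran from 0.144 to 0.385.

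**Figure D4:**
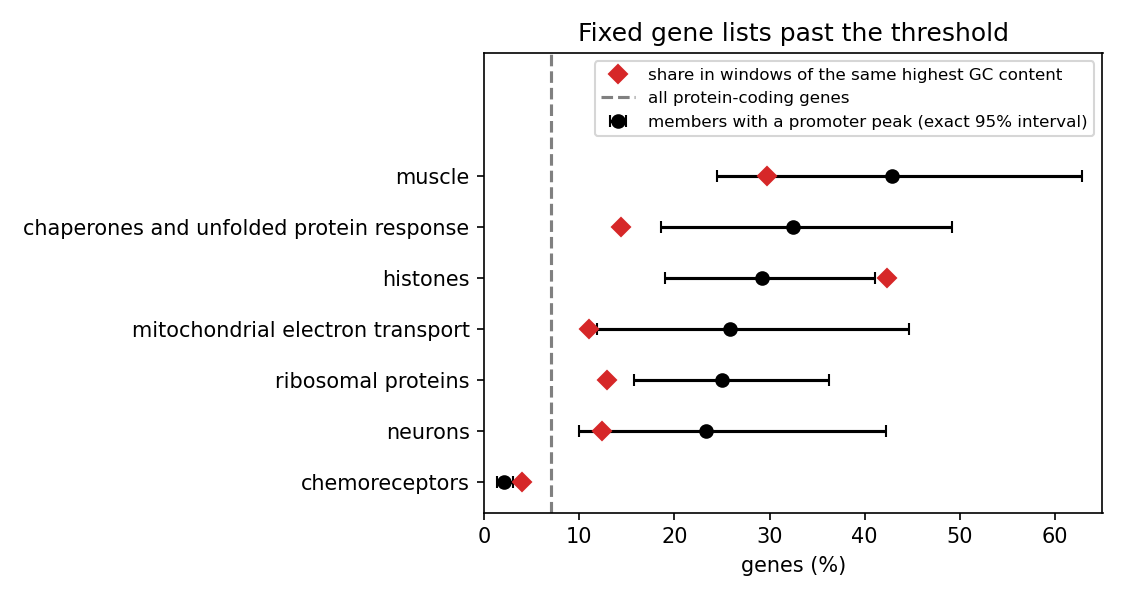
Percentage of genes with a promoter peak (x axis) in the 7 lists past the threshold (y axis). Circles are observed shares with exact 95% intervals, diamonds the share expected in windows of the same highest GC content, and the dashed line all protein-coding genes (6.99%); histones lie below their diamond and ribosomal protein genes above it.

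Of the 175 gene name classes, 4 departed from background, all upward. They were his (the histones), lin (12 of 47 genes, odds ratio 4.59, adjusted exact p = 0.0035), rpl (12 of 47, the same values) and unc. The lin class collects genes found through defects in cell lineage. Its strongest members were lin-66 (1342), lin-59 (585), which encodes a SET-domain protein, and lin-9 (542). The strongest of the unc class, named for uncoordinated movement, were unc-115 (915), the homeobox gene unc-42 (695) and unc-60. In GC strata, lin kept the call (ratio 2.46, adjusted exact p = 0.024) and the other 3 did not. The lin call was lost in replicate 1 alone, the unc call in replicate 2 alone, and all 4 for the peaks of highest signal. Against genes with a ranked peak as background only his kept the call. With the nearest gene start within 1000 bp in place of the window his lost it, and within the same window all 4 kept it.

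Promoter summits carried GA-rich sequence more often than matched windows. Of 1287 promoter summits, 638 had a control window of the same GC content, and the shares below cover only those. A GA repeat lay in 10% of summit windows (interval 7.81 to 12.6) and 2.19% of controls (odds ratio 4.97, adjusted Fisher exact p = 6.1e-08). A site like that of EOR-1, a zinc finger transcription factor, lay in 9.72% and 2.98% (odds ratio 3.51, adjusted exact p = 8.2e-06). The sizes of these odds ratios depended on the peak set. That of the GA repeat was 3.25 both in replicate 2 alone and for the peaks of highest signal, and that of the EOR-1-like site was 6.19 with the second list and 11.5 for the peaks of highest signal. The CAGCTG E-box lay in 10.8% and 5.33% (odds ratio 2.15, adjusted exact p = 0.0029), a call that was lost with the second list, for the peaks of highest signal, and in replicates 2 and 1 alone (adjusted exact p = 0.074, 0.29, 0.37 and 0.31). The EOR-1-like call and the E-box call were lost in windows of 50 bp to each side (adjusted exact p = 0.053 and 0.60). The other 17 motifs, including GATA, heat shock and homeodomain sites, did not pass. Of these, the E2F site passed in replicate 2 alone (odds ratio 2.96, adjusted exact p = 3.1e-04) and the FoxA site, less often at summits, in replicate 1 alone (0.634, adjusted exact p = 0.0028).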

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

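No paired analysis was possible because there is 1 group. Alternatives using GC content, gene bodies, 1 summit per interval or the nearest start within the same window were chosen after seeing the data. Of 156 alternative values, 110 kept their direction and side of the threshold or moved little, 24 counts or shares moved, 15 lost the threshold, 5 passed it newly and 2 reversed. The cause was not tested for any change below unless construction shows it. Keeping the peaks of highest signal left 2898 peaks and 753 genes with a promoter peak, by construction, and 0 gene classes. It raised the shared percentage of replicate 2 to 81.7%, which was 59.8% for overlap of at least 50% of both peaks and 74.7% for summits within 100 bp. Signal correlation was 0.745 for summits within 50 bp and 0.769 over all ranked peaks. The promoter fold of 1.03 became 1.05 with the second list, 1.05 with 1 summit per interval, 1.08 with 500 bp upstream and 1.23 at equal GC content, each past the threshold, and 1.01 to 1.16 with each replicate left out. The fold for X was 0.943 for the peaks of highest signal and 0.937 to 0.980 with each replicate left out, and it reversed to 1.03 at equal GC content. Genes with a promoter peak numbered 865 with 500 bp upstream and 2524 with 2000 bp upstream and 500 bp downstream, by construction. The 7 gene lists became 11 in that wider window, 12 with the nearest start within 1000 bp in place of the window (7 in the same window), 2 against genes with a ranked peak, 4 in GC strata and 15 by gene body, and 6 with either replicate left out, not the same 6. Histones reversed to 0.689 in GC strata. The 4 classes became 9 with the second list, 13 in the wider window, 12 with the nearest start within 1000 bp (5 in the same window), 1 against genes with a ranked peak and 1 in GC strata, and 5 with either replicate left out, not the same 5. The 3 motifs became 10 against flanking sequence and 1 in shorter windows. Read depth is unknown, and the number of peaks called depends on it.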

Other observations

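Every test in this part was chosen after its result, or a part of it, was seen, except the tests of replicate sharing at equal GC content and of multi-copy against single-copy tRNA genes. Counting summits anywhere in the gene body gave another picture than gene starts. Of 156 cuticle collagen genes, 132 (84.6%) had a summit in the body, against 12.5% of other genes (odds ratio 38.6, adjusted Fisher exact p = 8.6e-91), while 8 had a promoter peak. The same held for 5 of 6 vitellogenin genes, which encode yolk proteins (adjusted exact p = 6.1e-04), and 20 of 30 hypodermis genes (adjusted exact p = 9.7e-11). By gene body the calls for histones (odds ratio 1.08, adjusted exact p = 0.86) and electron transport (2.33, adjusted exact p = 0.083) were lost. In strata of GC content and gene length, 131 collagen genes were expected, a ratio of 1.01 (adjusted exact p = 0.92). The vitellogenin and hypodermis calls were lost there too (1.36, adjusted exact p = 0.59, and 1.09, adjusted exact p = 0.71). Chaperones passed above expectation in these strata (1.75, adjusted exact p = 0.033). Histones (0.562, adjusted exact p = 0.033) and chemoreceptors (0.621, adjusted exact p = 2.2e-05) passed below it.

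Genes of some noncoding classes carried summits within 200 bp of their starts at rates that departed from windows of the same GC content. Of 7764 ncRNA genes, 658 had a conservative summit where 413 were expected (adjusted exact stratified p = 4.0e-43). Of 346 snoRNA genes, 46 had one where 23.7 were expected (adjusted exact p = 2.8e-07), a ratio of 1.94 that was 1.97 in replicate 1 alone and 3.01 in replicate 2 alone, a difference that was not tested. Of 15363 piRNA genes, 17 had one where 57.0 were expected (adjusted exact p = 1.1e-12). Pseudogenes did not depart (ratio 0.822, adjusted exact p = 0.12), the departure of miRNA genes (0.580, adjusted exact p = 0.036) was lost in each replicate alone, and protein-coding starts departed upward (1.2, adjusted exact p = 3.2e-06). No summit was called at 20 rRNA genes, where 5.59 were expected, which allows a share of up to 16.8%. Whether reads could be placed at these genes was not tested. Peaks of low GC content, under 45%, numbered 211. Of these, 69 (32.7%) lay in gene start windows, against 21.9% of all tiles under 45% GC (exact binomial p = 3.1e-04). GC content was not matched within that range, so a remaining difference in it is not excluded. Genes there, named after their values were seen, included the heat shock protein 70 gene hsp-1 (signal 206, 39.3% GC) and the cytochrome c oxidase gene cox-5A (194, 42.3% GC).

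The calling rate rose with GC content from 0.0161% of tiles under 35% GC to 66.6% at 60% or more. Recognition of CpG is argued against as the whole cause among tiles of 50% GC or more, the only ones tested for it. At equal GC content the CpG-rich part of these tiles was called 1.103 times as often as the CpG-poor part (exact stratified p = 3.0e-05). At least 2 times was required, a limit set after the data were seen, so a smaller contribution of CpG is left open. Binding in coding sequence is argued against as the whole cause by a ratio of 0.906 over all tiles at equal GC content. That deficit was not seen among tiles of 60% GC or more. There 68.5% of coding exon tiles were called (interval 64.1 to 72.7), against 66.25% in introns and 62.5% in intergenic DNA (interval 55.8 to 68.9). GC content alone is argued against as well: tiles called in both replicates were 2.094 times the number expected from it, and 1.95 times with the surrounding kilobase also held fixed. Recovery or amplification of GC-rich fragments that differs from the control may contribute. Coding exon, untranslated exon, intron and intergenic tiles differed by up to 1.53 times at equal GC content. Noncoding gene classes lay further apart, with ratios such as 0.298 for piRNA and 2.81 for tRNA genes in the conservative list. The comparison therefore depends on the categories chosen and does not decide the question. A preference of the tagged protein for GC-rich DNA was not tested, and the control was not analysed here.

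For the 6 gene lists above background at promoters, GC content was measured as the highest in the window. By that measure it is argued against as the whole cause for ribosomal proteins (1.934 times the expected number), chaperones (2.261) and electron transport (2.339). For histones no excess remained (0.689). For muscle (1.442) and neurons (1.886) GC content cannot be told apart from an excess of their own. Peaks nearer to another protein-coding gene start whose window also holds them are argued against as the whole cause. For this, each summit was counted only for the nearest of the protein-coding gene starts whose windows hold it. The odds ratios were then 4.126 for ribosomal proteins, 3.084 for histones, 11.592 for muscle, 4.683 for neurons, 4.473 for chaperones and 4.488 for electron transport, all past the threshold. Histone genes with a peak fell from 21 to 12 and chaperone genes from 13 to 9. Summits inside the body of a neighbouring gene, or at a noncoding gene, could still be counted, so their part is left open. A candidate explanation for the remaining excess is signal that immunoprecipitation gives at highly transcribed genes whatever the tagged protein, and binding of SET-16 is another. No expression values or untagged animals were used here, so neither was tested.

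Genes for tRNA had a summit in replicate 2 at 126 of 612 and in replicate 1 at 57, with 46 in both. GC content is argued against, with 5.139 times the expected number in replicate 2 and 1.72 in replicate 1. Reads shared between identical copies may account for part, since multi-copy genes had higher odds of a summit than single-copy genes (odds ratio 2.078, Fisher exact p = 0.0065). In replicate 1 they did not pass the threshold (odds ratio 1.30, Fisher exact p = 0.51), and the difference between replicates was not tested. In the conservative list the odds ratio was 2.15 (Fisher exact p = 0.012), and 96 tRNA genes had a summit where 34.2 were expected from GC content. Shared reads are argued against for the 143 genes with no identical copy. Of these, 18 had a replicate 2 summit, 2.800 times the expected number (exact stratified p = 9.4e-06), though near-identical copies were not counted. No biological explanation was tested, as both replicates belong to 1 group.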
